A study of Zea mays with 10 samples.

How the data were processed

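Small RNA was extracted from young maize leaves grown in a greenhouse with a 12-hour light cycle, enriched from total RNA by polyethylene glycol precipitation, purified from polyacrylamide gels and made into libraries with the ScriptMiner small RNA-Seq kit, per the labels' protocols. Bowtie is named without a version or a role in the submitters' processing notes. Adapter trimming, genome build and filters are not recorded.

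The authors deposited 1 list per library of distinct sequences of 18 to 26 nt, each with a value in RPM. The file names say TPM, but the values of each library add up to 1000000 without any length correction, and all of them (100% in each of the 10 libraries, within 0.01 of a read, over 67914 to 1082352 values per library) are whole multiples of the smallest one, so whole read numbers could be recovered. The plan fixed before the data were examined spoke of TPM and of 18 to 30 nt, and both were read as RPM and 18 to 26 nt. Sequences with N and pieces of the 5' adapter are present, and whether the lists were limited to genome matches was not tested. Totals recovered this way ranged from 128369 to 3435369 reads, and they count reads of 18 to 26 nt only. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Intervals are at the 95% level (Wilson or exact binomial for shares, Poisson for reads), and a count of 0 is given a floor of 3 counts.

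Each tag's value was taken as log2(RPM + 1). The test was limma (version 3.58.1, with a trend) in 1 fit of all 10 libraries, 5 groups of 2, without a replicate block, on 15724 tags with a mean of at least 5 RPM, adjusted by Benjamini-Hochberg at a threshold of 0.05. All groups shared 1 estimate of the spread because groups of 2 give too few degrees of freedom alone. A second limma fit held 50 summary features: miRNA family sums of exact matches, Mu TIR sums, RNA fragment sums and length classes. The 29 miRNA and tasiRNA families, with 65 mature sequences in 9 lists (phase change, tasiRNA and polarity, auxin, leaf growth, silencing machinery, copper, phosphate and sulfate, other leaf, reproductive phasiRNA), the TIR primer sequence and the RNA fragments were written from memory before the data were examined, and 27 families had reads. Family p-values given over the list alone were adjusted over all measured families of the 9 lists together, 27 in the main fit. They were not adjusted within each list. TIR tags share an exact run of 18 nt with the primer sequence, and as an alternative with a repeat extended over 15-nt steps supported by at least 10 distinct tags. Shares of 24-nt reads were also compared by an exact permutation test over the 6 regroupings of 2 against 2, whose smallest two-sided p is 0.333. Named by rule were every family and fragment, the TIR sums, and per comparison the 5 tags with the largest rise and the 5 with the largest fall among those past the threshold whose groups did not overlap, after tags sharing 18 nt were collapsed. Python 3.11.15 and R 4.3.3 were used.

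Alternatives fixed before the data were examined were a replicate block, pseudocounts of 0.5 and 5, median-of-ratios scaling over the 5151 tags seen in every library, array weights, no filter on level (tags seen in at least 2 libraries), a mean of at least 20 RPM, tags of 20 to 24 nt only, 3' variants of up to 2 nt, families with a mean of at least 5 RPM only, the 24-nt share among 20 to 24 nt, the 24-nt class without miRNA tags, TIR runs of 16 or 20 nt, the extended repeat, and each library left out in turn. Added after the data were seen were edgeR (version 4.0.16, quasi-likelihood) on the recovered reads, the percent of 25- and 26-nt reads as a covariate, and leaving out MuDR only replicate 2 and F1 leaf 2 replicate 1 together, whose percent of 25- and 26-nt reads lies above 20 while that of their partner lies below 20. F1 leaf 6 replicate 1 meets the same condition (24.3 against 19.2) and was kept in that fit, so a last alternative left out all 3. Fits with libraries left out used tags seen in at least 2 of the remaining libraries, a filter set after tags without variance were met. Where a group is left with 1 library, that library is assumed to vary like the other groups.

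On simulated data for the comparison of Muk only with no MuDR no Muk (15724 tags, 100 changed per fold size), limma recovered 11% of 16-fold and 45% of 64-fold changes at the estimated spread with 1 unchanged tag called, and edgeR recovered 0% of both. With the dispersion, which scales with the square of the coefficient of variation, cut to 10% of its estimate, limma recovered 87% and 100%. In that setting edgeR recovered 100% of both with 5 unchanged tags called. The coefficient of variation at the median dispersion was 96.0%. Tags were drawn independently of each other, so apart from the planted changes the simulated libraries had no split shared by many tags. The unchanged tags called therefore do not measure false calls under such a split. The same holds for the simulated contigs below.

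For the closing section, 22-nt tags of all libraries together were joined into contigs over 15-nt steps without use of the groups, and the contigs whose reads peaked at 22 nt with 20% to 80% on the plus strand were kept. Reads in them were compared between the 6 libraries with Muk and the 4 without it by edgeR, scaled to all contig reads. This test found all 15 of 15 contigs simulated at 32-fold, with 3 unchanged contigs called, among 149. No genome, MuDR or Muk sequence was used here, so neither tags nor contigs were given coordinates or assigned to genes. The name and length of 1 contig are not reported here.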

Results

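Small RNAs were sequenced from young leaves of maize (Zea mays) plants that differed in 2 loci of the Mutator transposon system. MuDR is the autonomous element of that system, and Mu killer (Muk) is a rearranged, inverted duplicate of part of MuDR that silences it. The 10 libraries fell into 5 groups of 2. Leaf 2 was sampled from a tester control with neither locus (no MuDR no Muk), from plants with MuDR only, from plants with Muk only and from F1 plants with both, and leaf 6 was sampled from the F1. The series title names silencing of Mu elements by distinct populations of small RNAs, and the comparisons below address which small RNAs differed between these genotypes and between the F1 leaves. Each deposited value gave the reads of 1 distinct sequence (a tag) relative to all reads of 18 to 26 nt (RPM). No reference genome was used here, so tags carry no coordinates and are identified by sequence.

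The no MuDR no Muk libraries held 1263022 and 1227744 reads of 18 to 26 nt in replicates 1 and 2. The MuDR only libraries held 3435369 and 128369 reads, the Muk only libraries 3273338 and 1925789, the F1 leaf 2 libraries 1800055 and 2727807, and the F1 leaf 6 libraries 722618 and 1218898. A single read was worth 7.79 RPM in MuDR only replicate 2 and 0.291 RPM in MuDR only replicate 1. The libraries held 4063745 distinct tags in all, of which 606722 occurred in at least 2 libraries and 5151 in all 10. Intervals and detection floors below cover counting error only, and the p-values measure only the spread between these samples, because the labels do not say whether replicates came from separate plants.

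The 24-nt class, which in plants holds mostly heterochromatic siRNAs, made up 14.3% ± 0.972 of reads (SD, n = 2) in no MuDR no Muk, 14.9% ± 3.09 in MuDR only, 12.8% ± 0.387 in Muk only, 14.6% ± 3.40 in F1 leaf 2 and 11.8% ± 2.47 in F1 leaf 6. Replicates of 1 genotype differed in length profile. Reads of 25 and 26 nt made up 29.8% and 23.2% of the no MuDR no Muk libraries, 12.1% and 23.5% of MuDR only, 13.3% and 16.1% of Muk only, 26.5% and 16.5% of F1 leaf 2, and 24.3% and 19.2% of F1 leaf 6. The Wilson 95% intervals of these shares were at most 0.464 percentage points wide. Pieces of the 5' sequencing adapter made up 0.136% to 5.87% of reads, and reads with an uncalled base made up 0.0931% to 9.62%. Across 15724 tags, which are not independent replicates, log2 levels correlated at a Pearson r of 0.75 between the no MuDR no Muk replicates and 0.81 between the Muk only replicates. The correlation was 0.12 between the MuDR only replicates, 0.28 between the F1 leaf 2 replicates and 0.31 between the F1 leaf 6 replicates. MuDR only replicate 1 and F1 leaf 2 replicate 2 correlated with each other at 0.86 and with the Muk only libraries at 0.73 to 0.81.

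**Figure D1:**
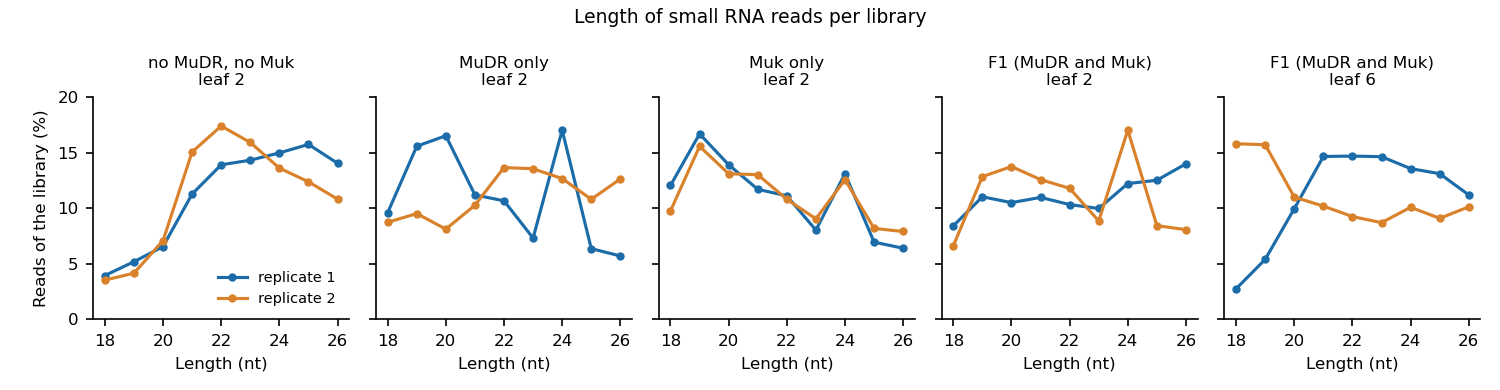
Length of small RNA reads in each library: percent of the library's reads (y axis) at each length in nt (x axis), 1 panel per group, 1 line per replicate. MuDR only replicate 1 and F1 leaf 2 replicate 2 peak at 24 nt with 17% each, while their partners hold more reads of 25 and 26 nt.

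Small RNAs of the Mu terminal inverted repeat (TIR), the end sequence shared by Mu elements, were scarce in every group. Tags sharing an exact run of 18 nt with a 32-nt TIR primer sequence added up to 93 reads over all 10 libraries, of which 89 ran in the strand that reads into the element (95.7%, exact 95% interval 89.4 to 98.8). These reads came from 50 distinct tags on the inward strand and 4 on the outward strand. Summed over all lengths they reached 2.43 ± 2.32 RPM (SD, n = 2) in no MuDR no Muk, 6.51 ± 1.80 in MuDR only, 5.87 ± 0.518 in Muk only, 6.51 ± 8.42 in F1 leaf 2 and 1.79 ± 1.38 in F1 leaf 6. When the repeat was extended from overlapping tags to 60 or 61 nt, 315 reads matched and 288 of them were inward (91.4%, exact 95% interval 87.8 to 94.3). The extended 24-nt reads pooled over both libraries of a group amounted to 1.61 RPM in no MuDR no Muk (95% Poisson interval 0.438 to 4.11), 5.05 RPM in MuDR only (2.99 to 7.98), 14 RPM in Muk only (11 to 17.7), 17.4 RPM in F1 leaf 2 (13.8 to 21.7) and 4.12 RPM in F1 leaf 6 (1.78 to 8.12). Single F1 leaf 2 libraries held 5.00 RPM (2.29 to 9.49) in replicate 1 and 25.7 RPM (20.0 to 32.4) in replicate 2, and MuDR only replicate 2 held 0 reads, where 3 reads would have been 23.4 RPM. No comparison of TIR small RNAs between groups passed the limma test, with either form of the repeat.

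**Figure D2:**
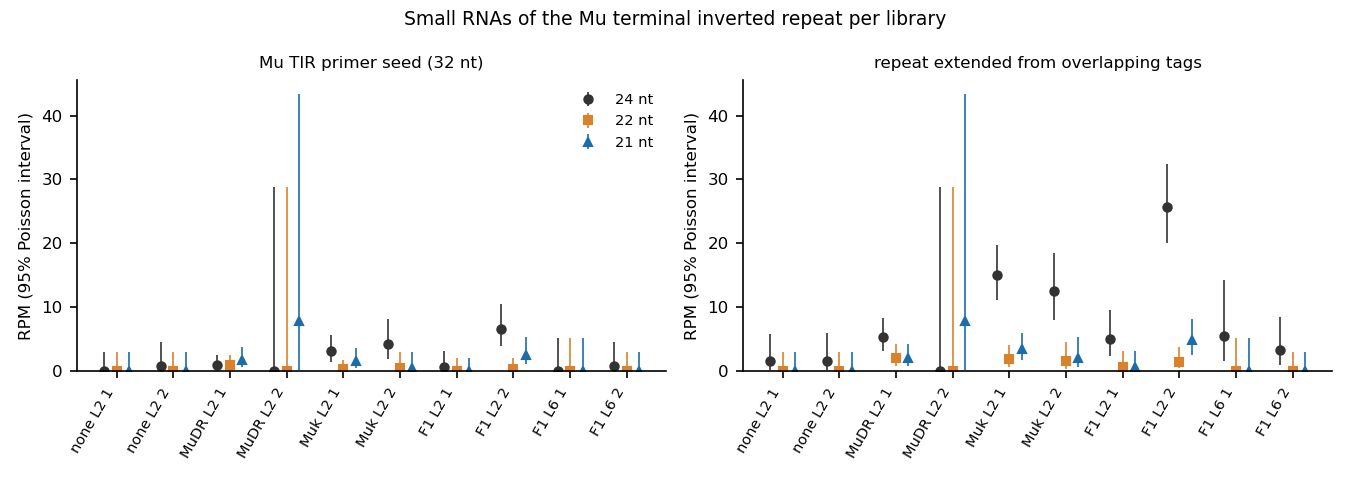
Reads of the Mu terminal inverted repeat in RPM (y axis) at 24, 22 and 21 nt in each library (x axis: none, no MuDR no Muk; L2, leaf 2; L6, leaf 6; 1 and 2, replicates), with 95% Poisson intervals, for the primer sequence (left) and the extended repeat (right). The Muk only libraries and F1 leaf 2 replicate 2 hold 12.5 to 25.7 RPM of extended 24-nt reads, and MuDR only replicate 2 is too shallow to place.

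Muk only against no MuDR no Muk asks which small RNAs accompany the silencing locus without its target. miR156, which represses SPL transcription factors and marks the juvenile phase, rose from 558 ± 4.37 RPM (SD, n = 2) in the control to 20385 ± 1225 RPM in Muk only (log2 fold change 5.19, SE 1.35, limma adjusted p = 0.0136 over the list alone and 0.0126 over all 50 summary features). It was the only family of the phase change list to pass of 3 measured, beside miR172, its antagonist in phase change, at 0 and 1.37 ± 1.94 RPM, and miR529 at 0 and 0.153 ± 0.216 RPM. The 19-nt length class rose from 46591 ± 7320 to 161481 ± 7918 RPM (log2 fold change 1.80, limma adjusted p = 0.0126).

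None of the other lists gave a family past the limma threshold in Muk only, adjusted over all 27 measured families together. In the silencing machinery list (0 of 2), miR168, which targets ARGONAUTE1, stood at 115 ± 107 RPM in the control and 1836 ± 1219 in Muk only. Its log2 fold change was 4.20 (SE 1.46, limma adjusted p = 0.0926 over the 27 measured families). The other member, miR162, which targets DICER-LIKE1, stood at 2.02 ± 1.74 and 49.3 ± 3.68 RPM. In the copper list (0 of 4), miR528 stood at 10.4 ± 2.06 and 114 ± 61.9 RPM, miR397 at 2.42 ± 1.18 and 88.1 ± 10.5 RPM, and miR398 was at 0 in both control libraries and at 15.9 ± 0.434 RPM in Muk only. The leaf growth list (0 of 7) included miR159, which targets GAMYB factors, at 55.8 ± 35.2 and 252 ± 20.4 RPM. The tasiRNA and polarity list (0 of 3) included miR166, which targets HD-ZIP III genes, at 0.396 ± 0.560 and 70.1 ± 8.83 RPM. The auxin list (0 of 4) included miR164, which targets NAC genes, at 8.48 ± 5.28 and 89.9 ± 55.0 RPM. The phosphate and sulfate list (0 of 3) included miR827 at 0 and 9.90 ± 3.72 RPM, and the reproductive phasiRNA list had 1 measured member, miR2275, at 0 in these 4 libraries. miR1432, alone on its list, and miR2118 were not detected in any library. In all, 24 of 27 measured families lay above the control, with RPM scaling and with median-of-ratios scaling, and 1 passed adjusted over the list alone. The percent of 25- and 26-nt reads moved with these families, at 13.3 and 16.1 in Muk only and 29.8 and 23.2 in the control.

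**Figure D3:**
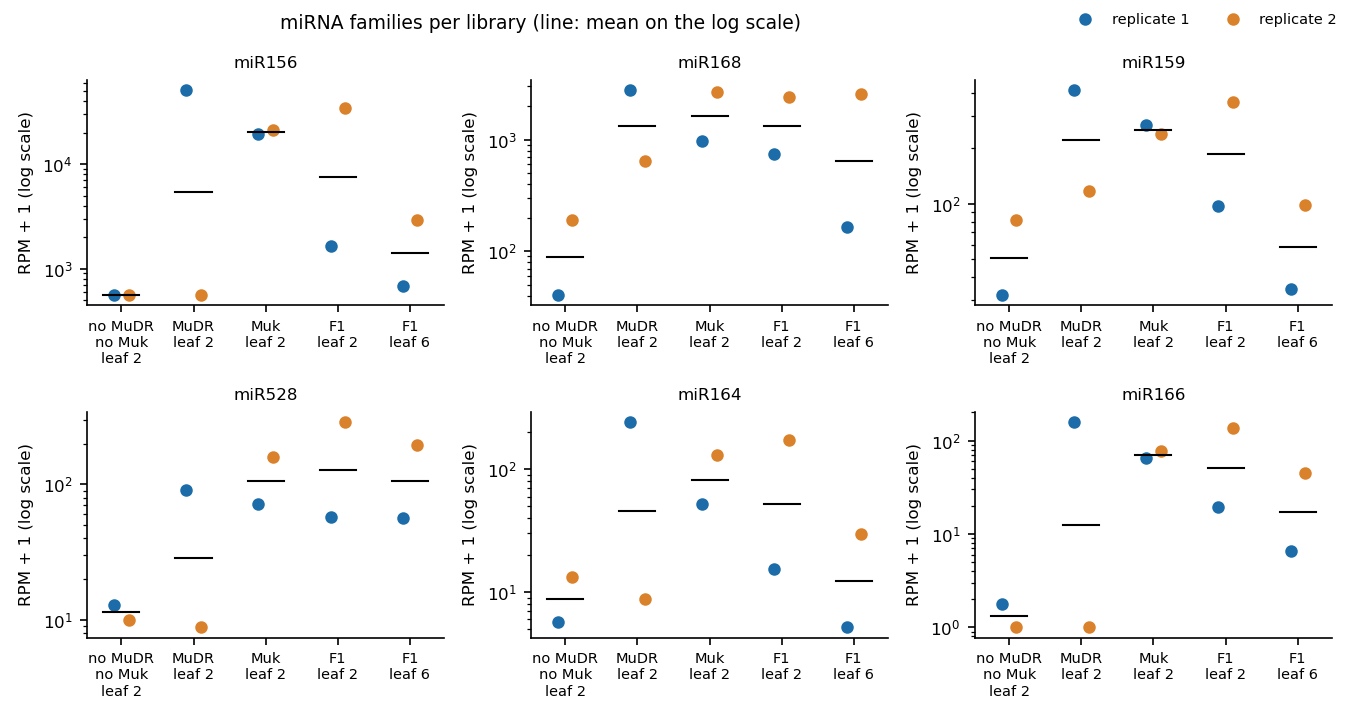
Levels of 6 miRNA families in each library as RPM + 1 on a log scale (y axis) by group (x axis); points are replicates and lines the mean on the log scale. miR156 stands at 555 and 561 RPM in the control libraries and at 19519 and 21251 RPM in the Muk only libraries, while the MuDR only libraries hold 51236 and 561 RPM.

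Among single tags, 340 passed the limma threshold between Muk only and no MuDR no Muk, 288 higher and 52 lower in Muk only. Of the 288 higher tags, 221 were 18 to 20 nt long and 10 were 24 nt long, with a median length of 19 nt. The median log2 fold change was 5.92, or 5.85 with the 109 tags absent from both control libraries set at their bound against a floor of 3 reads over the group, while the median over all tags tested was −0.22. The tag TAATTCATGATCTGGCATG averaged 10234 ± 5579 RPM in Muk only and 22.6 ± 15.2 in the control (log2 fold change 8.81, SE 1.67, limma adjusted p = 0.00870). GGTAGTTCGACCGTGGATT averaged 24374 ± 8114 RPM in Muk only and 53.9 ± 6.76 in the control, GGTAGGTCGACCGTGGATT averaged 1402 ± 406 and 4.06 ± 4.62 RPM, and GGCGGAATGCTCGAGCTGC averaged 1412 ± 172 and 3.63 ± 1.78 RPM. CCGGGGGACGGACCGGGAA averaged 386 ± 101 RPM and had no read in either control library, so it was at least 320.4-fold higher against a floor of 3 reads over the group. One tag of the miRNA list passed, miR166 TCGGACCAGGCTTCATTCCCC, with a log2 fold change of 5.52. Of the 52 lower tags, 24 held an uncalled base or a piece of the 5' adapter. The lower tags with the largest changes included the adapter pieces GTTCTACAGTCCGACGAT, at 564 ± 434 RPM in the control and 5.73 ± 2.92 in Muk only, AGTTCNACAGTCCGACGATC, at 112 ± 13 and 0.306 ± 0.432 RPM, and AGAGTNCTACAGTCCGACGATC, at 83.6 ± 7.35 and 0.153 ± 0.216 RPM. The others were CTAGTNAATACGTGTGCTTGGGAG, at 279 ± 38.0 and 2.05 ± 1.43 RPM, and AGACTTTGGGCTATCCGGACACAT, at 1577 ± 1137 and 21.2 ± 19.2 RPM.

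The library profile followed the same split as this comparison: both control libraries held over 20% and both Muk only libraries under 20% of 25- and 26-nt reads, so profile and genotype cannot be separated within these 4 libraries. With that percent as a covariate, chosen after the data were seen, 0 tags and 0 families passed limma. The tag count was 0 with edgeR on recovered reads (2469 higher and 1581 lower at an unadjusted p under 0.05). The lowest edgeR adjusted p was 0.055 among the higher and among the lower tags, just above the threshold. The tag count was 0 with median-of-ratios scaling, 2 with a pseudocount of 5 and 7379 with array weights (3853 higher and 3526 lower). It fell to 0 without any 1 of the 6 libraries of no MuDR no Muk, Muk only and F1 leaf 2, and rose to 966 without MuDR only replicate 1. With MuDR only replicate 2, F1 leaf 2 replicate 1 and F1 leaf 6 replicate 1 left out, every library above 20% of 25- and 26-nt reads whose partner lies below 20%, 5721 tags and 17 families passed here, 5633 and 23 for MuDR only and 4234 and 23 for the F1 against the control. In that fit, chosen after the data were seen, only the control libraries lie above 20%, so profile and genotype are confounded in all of these counts, and the spread rests on the control and Muk only pairs. The miR156 call held in 15 of 25 other settings of the same fit, with limma adjusted p over the list alone from 4.35e-07 to 0.997. In 9 of the 10 settings that ended the call its log2 fold change stayed at 5.13 to 5.86 while the SE was 1.5 to 2.94, and the covariate alone lowered it, to 0.24 (SE 1.22). The 288 higher tags were also abundant in MuDR only replicate 1, which carries no Muk, at a median of 5.78 above the control mean on the log2 scale, against 0 in MuDR only replicate 2. Mu TIR small RNAs did not pass (log2 fold change 1.19, SE 1.60, limma adjusted p = 0.578). Their reads of 24 nt numbered 18 in Muk only (3.46 RPM pooled) and 1 in the control (0.401 RPM pooled). The 24-nt share was lower by 1.46 percentage points in Muk only, a difference of the means that an exact permutation test gave a two-sided p of 0.333, the smallest that 2 against 2 libraries allow.

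**Figure D4:**
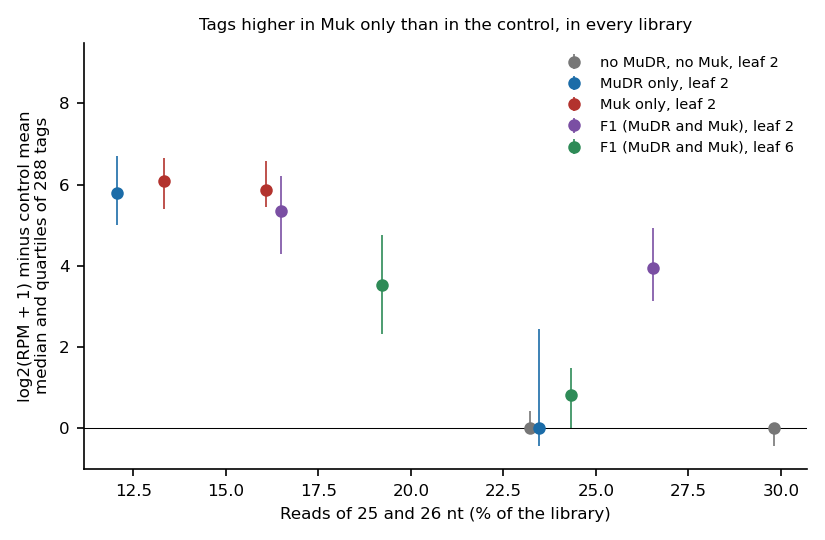
Median and quartiles (points and bars) of log2(RPM + 1) minus the control mean over the 288 tags higher in Muk only (y axis), plotted against the percent of reads of 25 and 26 nt in each library (x axis); colours are groups. MuDR only replicate 1, with 12.1% of such reads, lies at 5.78, next to the Muk only libraries at 6.09 and 5.87.

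MuDR only against no MuDR no Muk asks which small RNAs accompany an active MuDR element. No family of any list passed limma adjusted over the list alone (2 of 27 at an unadjusted p under 0.05, both higher). Those were miR168, at 115 ± 107 RPM in the control and 1704 ± 1507 in MuDR only, and miR156, at 558 ± 4.37 and 25898 ± 35832 RPM. Replicate 1 of MuDR only held 51236 RPM of miR156 and replicate 2 held 561. By list, 0 of 3 families passed for phase change, 0 of 3 for tasiRNA and polarity, 0 of 4 for auxin, 0 of 7 for leaf growth, 0 of 2 for silencing machinery, 0 of 4 for copper, 0 of 3 for phosphate and sulfate and 0 of 1 for reproductive phasiRNA.

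TIR reads of 21 nt numbered 7 in MuDR only and 0 in the control, where 3 reads would have given 1.20 RPM. All 7 lay on the inward strand, and the sums did not pass (unadjusted p = 0.00274 in limma, adjusted p = 0.0686 over all summary features). The mean of 4.77 ± 4.27 RPM in MuDR only rested on 6 reads in replicate 1, at 1.75 RPM, and on a single read in the shallow replicate 2, at 7.79 RPM, while the pooled value was 1.96 RPM (95% Poisson interval 0.790 to 4.05). TIR small RNAs of all lengths gave a log2 fold change of 1.30 (SE 1.60, limma adjusted p = 0.600). The 24-nt share was 0.554 percentage points higher in MuDR only (exact permutation test, two-sided p = 1). Of single tags, 0 passed limma (913 higher and 2992 lower at an unadjusted p under 0.05) and 0 passed edgeR (2304 and 1872). Leaving out either MuDR only library changed these counts, but the group then rested on 1 library. Where replicate 1 was left out, that was the shallow replicate 2. With MuDR only replicate 2 and F1 leaf 2 replicate 1 left out together, a setting chosen after the data were seen, 0 tags and 11 families passed, all higher in MuDR only, 3 of them below 1 RPM in every group of that fit.

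F1 against no MuDR no Muk, both in leaf 2, asks which small RNAs differ when MuDR is being silenced by Muk. No family passed limma over the list alone, and 7 of 27, all higher in the F1, had an unadjusted p under 0.05. miR156 stood at 558 ± 4.37 RPM in the control and 18202 ± 23424 in the F1 (log2 fold change 3.76, SE 1.35, limma adjusted p = 0.149 over the list alone). miR168 stood at 115 ± 107 and 1577 ± 1185 RPM, miR166 at 0.396 ± 0.560 and 76.8 ± 82.7 RPM, and miR408, of the copper list, at 0.407 ± 0.576 and 34.5 ± 33.1 RPM. The 3 others, miR394, miR398 and miR827, were at 0 in both control libraries and averaged 20.9 ± 17, 10.6 ± 7.87 and 9.92 ± 7.74 RPM in the F1. By list, 25 of 27 measured families lay above the control under both scalings and 0 passed.

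TIR reads of 24 nt numbered 19 in F1 leaf 2 (4.20 RPM pooled), of which 18 came from replicate 2, and 1 in the control (0.401 RPM pooled). The sum over all lengths gave a log2 fold change of 0.60 (SE 1.60, limma adjusted p = 0.788), and the 24-nt share differed by 0.327 percentage points (exact permutation test, two-sided p = 1). Of single tags, 0 passed limma (1096 higher and 1028 lower at an unadjusted p under 0.05) and 0 passed edgeR (2144 and 1133). The F1 replicates differed in their percent of 25- and 26-nt reads, 26.5 and 16.5, and without both doubted libraries, MuDR only replicate 2 and F1 leaf 2 replicate 1, 0 tags and 16 families passed, 4 of these below 1 RPM in every group of that fit. Without either MuDR only library, 9 families passed, and with array weights 33 tags did.

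F1 against MuDR only in leaf 2 asks what changes in MuDR plants when Muk is added. No family passed limma (0 at an unadjusted p under 0.05). miR528, which targets copper protein genes, had values of 171 ± 162 RPM in the F1 and 49.2 ± 58.5 in MuDR only (log2 fold change 2.17, SE 1.93), and miR156 had values of 18202 ± 23424 and 25898 ± 35832 RPM. The mean of miR156 was lower in the F1 while its log2 fold change was 0.49 (SE 1.35), so the 2 measures point in opposite directions. miR168 had values of 1577 ± 1185 and 1704 ± 1507 RPM. Of 27 families, 21 lay above MuDR only with RPM scaling and 18 with median-of-ratios scaling, and the median of all tags was itself 0.69 higher in the F1 on the log2 scale.

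TIR reads of 24 nt numbered 19 in the F1, most of them from replicate 2, and 3 in MuDR only (log2 fold change 1.33, SE 0.85). Those of 21 nt numbered 7 in each group. The sum over all lengths gave a log2 fold change of −0.69 (SE 1.60, limma adjusted p = 0.986), which changed sign to 0.87 with the extended repeat. The 24-nt share was 0.226 percentage points lower in the F1 (exact permutation test, two-sided p = 0.667). Of single tags, 0 passed limma (478 higher and 259 lower at an unadjusted p under 0.05), while edgeR on recovered reads called 79, all lower in the F1 (675 higher and 727 lower at an unadjusted p under 0.05). The limma count also changed without either MuDR only library, where that group rested on a single library. Where replicate 1 was left out, that was the shallow replicate 2.

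F1 against Muk only in leaf 2 asks what MuDR adds where Muk is present. No family passed limma (0 at an unadjusted p under 0.05). miR156 stood at 18202 ± 23424 RPM in the F1 and 20385 ± 1225 in Muk only (log2 fold change −1.43, SE 1.35), miR159 at 227 ± 185 and 252 ± 20.4 RPM, miR166 at 76.8 ± 82.7 and 70.1 ± 8.83 RPM, and miR397 at 84.7 ± 90.7 and 88.1 ± 10.5 RPM. Of 27 families, 21 lay below Muk only with RPM scaling and 17 with median-of-ratios scaling. TIR reads of 24 nt numbered 19 in the F1 and 18 in Muk only, and the sum over all lengths gave a log2 fold change of −0.58 (SE 1.60, limma adjusted p = 0.970), with the opposite sign, 0.97, without both doubted libraries. The 24-nt share was 1.78 percentage points higher in the F1 (exact permutation test, two-sided p = 1). Of single tags, 0 passed limma (27 higher and 161 lower at an unadjusted p under 0.05) and 0 passed edgeR (128 and 195). With both doubted libraries left out, 0 tags and 4 families passed, 3 of them below 1 RPM in every group of that fit and the other, miR529, at 1.10 RPM from 3 reads.

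F1 leaf 6 against F1 leaf 2 asks whether small RNAs of the F1 differ between an early and a later leaf. No family passed limma (0 at an unadjusted p under 0.05). miR156, which declines as maize shoots leave the juvenile phase, had values of 18202 ± 23424 RPM in leaf 2 and 1798 ± 1588 in leaf 6 (log2 fold change −2.43, SE 1.35, limma adjusted p = 0.590 over the list alone). miR172, which rises in the adult phase, had values of 0.367 ± 0.518 and 2.20 ± 0.797 RPM (log2 fold change 1.26, SE 0.64). miR168 had values of 1577 ± 1185 and 1355 ± 1685 RPM, and miR164 had values of 93.6 ± 112 and 16.4 ± 17.4 RPM. Of 27 families, 23 lay below leaf 2 under both scalings.

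TIR reads of 24 nt numbered 1 in leaf 6 and 19 in leaf 2, and those of 21 nt 0 (upper Poisson limit 1.90 RPM) and 7 (1.55 RPM pooled). The sum over all lengths gave a log2 fold change of −0.81 (SE 1.60, limma adjusted p = 0.820), and the 24-nt share was 2.80 percentage points lower in leaf 6 (exact permutation test, two-sided p = 0.667). Of single tags, 0 passed limma (395 higher and 505 lower at an unadjusted p under 0.05) and 0 passed edgeR (818 and 658). Without both doubted libraries, 0 tags and 6 families passed, all lower in leaf 6, among them miR156 (log2 fold change −4.63, SE 0.92, limma adjusted p = 0.0310 over the list alone), and 4 of the 6 were below 1 RPM in every group of that fit. That exclusion is one-sided, since it drops the leaf 2 library rich in 25- and 26-nt reads (1639 RPM of miR156) and keeps F1 leaf 6 replicate 1, which is rich in them too (24.3%, 675 RPM). With that library left out as well, 1 library per leaf remained and the log2 fold change of miR156 was −3.57. Without F1 leaf 2 replicate 1 alone, 2 families passed.

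The interaction of MuDR and Muk in leaf 2 asks whether the F1 departs from the sum of both single-locus effects. miR156 had an interaction of −4.69 on the log2 scale (SE 1.91) and miR168 one of −4.19 (SE 2.06), neither past the limma threshold (adjusted p = 0.484 over the list alone for both). TIR reads of 21 nt had an interaction of −2.35 (SE 1.01, limma adjusted p = 0.255 over all summary features), which also rested on the 7.79 RPM given by 1 read in MuDR only replicate 2, and 5 of 50 summary features had an unadjusted p under 0.05. Of single tags, 0 passed limma (1375 higher and 746 lower at an unadjusted p under 0.05) and 0 passed edgeR (1766 and 1842). Without MuDR only replicate 2, 9 families passed, all negative, and without both doubted libraries 1 positive and 1 negative family passed, miR393 (0.45) and miR399 (−0.86), both below 1 RPM in every group of that fit. With F1 leaf 6 replicate 1 also left out, 1 positive and 12 negative families passed.

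Fragments that report on RNA quality did not pass limma in any of these comparisons. The 5' end of tRNA-Ala averaged 13.7 ± 1.41 RPM in no MuDR no Muk, 119 ± 129 in MuDR only, 50 ± 38.7 in Muk only, 30.7 ± 26.1 in F1 leaf 2 and 22 ± 9.54 in F1 leaf 6. The 5' end of tRNA-Glu averaged 2.40 ± 1.09, 27.2 ± 27.7, 6.20 ± 2.90, 8.29 ± 0.842 and 0.692 ± 0.979 RPM in the same order, and that of tRNA-Gly 3.56 ± 5.04, 1.60 ± 2.26, 5.57 ± 3.13, 6.38 ± 7.47 and 1.10 ± 0.398 RPM. The 5.8S ribosomal RNA core gave reads in Muk only replicate 1 alone, at a group mean of 0.917 ± 1.30 RPM, and so says nothing of RNA quality.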

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

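All tests of this part were chosen after the result was seen, except the 2 tests of the 340 tags between Muk only and no MuDR no Muk, which were written down before their values were seen.

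Outside the fixed lists, 7 contigs of 22-nt tags held 116 RPM in the lower of the 2 Muk only libraries, above both no MuDR no Muk libraries, which held 15 and 2.44 RPM. The contigs come from 149 kept of 505 assembled. By edgeR on reads scaled to all contig reads, 2 contigs passed between libraries with Muk and those without it (8 higher and 4 lower at an unadjusted p under 0.05), and 0 passed with library totals. They were an 80-nt contig, contig_AV (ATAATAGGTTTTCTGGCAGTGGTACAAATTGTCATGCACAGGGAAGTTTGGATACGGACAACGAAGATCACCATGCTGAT, log2 fold change 5.90, edgeR adjusted p = 0.00324), and a 40-nt contig, contig_FG (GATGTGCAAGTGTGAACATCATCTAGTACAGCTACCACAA, log2 fold change 5.58, edgeR adjusted p = 0.00516). The call of contig_FG rested on 38 reads in all. Replicates 1 and 2 held 17 and 1 of them in Muk only, 2 and 15 in F1 leaf 2, and 0 and 3 in F1 leaf 6. The libraries without Muk held none. The 5 other contigs of the 7 had an unadjusted p under 0.05 and a log2 fold change over 2. Together the 7 held 1504 reads in 461 distinct tags, 74.3% of them 22 nt long, with 466 reads on 1 strand and 1038 on the other. Their share of contig reads was 3.56% and 4.03% in Muk only (exact 95% intervals 3.25 to 3.89 and 3.53 to 4.59), 3.07% and 4.22% in F1 leaf 2 (2.39 to 3.88 and 3.91 to 4.56), and 4.56% and 7.09% in F1 leaf 6 (2.63 to 7.30 and 5.49 to 8.98). It was 0.00512% in MuDR only replicate 1 (1 of 19537 reads, 0.00013 to 0.0285), 0 of 173 reads in MuDR only replicate 2, with an upper limit of 2.11%, 0.354% in no MuDR no Muk replicate 2 (0.0731 to 1.03) and 3.11% in replicate 1 (1.88 to 4.81).

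The search and its settings were shaped by the data. Such sequences were first met in a search that used the groups, and the assembly without groups followed. Stricter first settings (contigs of at least 60 nt, 20 reads to start and 4 per step, in place of 40, 10 and 3) kept 31 contigs, of which 0 passed edgeR (2 higher and 0 lower at an unadjusted p under 0.05) and 0 shared 22 nt with the 7. Without MuDR only replicate 1, 0 contigs passed, without no MuDR no Muk replicate 1, the 7 passed and no other, and without each of the other 8 libraries, 2 passed.

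The 7 contigs were picked for this difference, so their shares restate it. A lack of 22-nt siRNA reads of any kind would lower the RPM of the 7 contigs but not their share of contig reads. The share was 0.00512% in MuDR only replicate 1 and 0.354% in no MuDR no Muk replicate 2. Since the contigs were picked on this share, its low values cannot decide against such a lack. The share was 3.11% in no MuDR no Muk replicate 1, and MuDR only replicate 2 held only 173 contig reads. The other 142 contigs stood at 1192 RPM in the lowest leaf 2 library with Muk. Of the 4 libraries without Muk, 2 lay below that beyond counting error, both no MuDR no Muk. Above it lay 1, MuDR only replicate 1 (5687 RPM). This comparison replaced 3 others made after the values were seen, and the count depends on the reference: 3 of 4 lay below the median of the libraries with Muk (1973 RPM), as did 3 of the 6 with Muk, and 0 of 4 below the lowest of these in either leaf (464 RPM). Chance could not be excluded: 5 of 100 splits of the 10 libraries into 6 and 4, the real one included, gave at least 2 contigs, and the highest other gave 8, by setting MuDR only replicate 1, both Muk only libraries and F1 leaf 2 replicate 2 apart, which follows the length profile of the libraries. Reads or tissue with Muk mixed into no MuDR no Muk replicate 1 may explain its share of 3.11%, within counting error of the pooled 3.96% of the libraries with Muk, but on the 2 called contigs alone that library held 1 of 611 reads (0.164%, 0.00414 to 0.908), and those were called partly for being low there. Muk as the source is a hypothesis: reads of the 7 contigs occurred in all 6 libraries with Muk, yet other loci from the Muk parent cannot be told apart from it without a Muk sequence to match.

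The 340 tags between Muk only and no MuDR no Muk were also weighed. A technical split of the libraries is a candidate explanation, since within MuDR only, F1 leaf 2 and F1 leaf 6 the replicate with fewer 25- and 26-nt reads held more of the 288 higher tags, by medians of 5.17, 1.37 and 2.74 on the log2 scale (smallest 1.3749). MuDR only replicate 1, without Muk, reached 97.8% of the Muk only median on the log2 scale. An effect of carrying Muk stays open beside it. On the log2 scale the median of these tags lay 3.94 above the control in F1 leaf 2 replicate 1 and 0.811 in F1 leaf 6 replicate 1. The Muk only median was 5.92, so these log2 values were 66.556% and 13.7% of it and are not shares of the RPM level. Both libraries are rich in 25- and 26-nt reads, so the libraries with Muk were split.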

How the results depend on the processing

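All planned settings were fixed before the data were examined, and edgeR, the 25- and 26-nt covariate, the fit without both doubted libraries (MuDR only replicate 2 and F1 leaf 2 replicate 1) and the fit also without F1 leaf 6 replicate 1 (3 out) were chosen after they were seen. Apart from leaving out single libraries, 64 of 84 values for tag counts, 42 of 60 for family counts, 53 of 60 for the 24-nt class and 60 of 66 for TIR small RNAs kept their direction and side of the threshold, or stayed within 1.5 times the count. Only Muk only against no MuDR no Muk had a main count above 0 (340 tags and 1 family). Most of the counts that held were therefore 0 in both fits. The counts of that comparison moved in most of these settings, as listed below. The cause was not tested for any change below unless said.

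For tags, Muk only against no MuDR no Muk (340) gave 2 with a pseudocount of 5, 0 with median-of-ratios scaling, 7379 with array weights (3853 higher, 3526 lower), 0 with no filter on level, 110 at a mean of at least 20, 146 at 20 to 24 nt, and 0 with the covariate, without both doubted libraries and with edgeR. With 3 out, MuDR only, Muk only and F1 against no MuDR no Muk gave 5633, 5721 and 4234. Array weights favour the Muk only libraries (4.12 against 0.394 for MuDR only). At 20 to 24 nt, MuDR only against no MuDR no Muk gave 9 and F1 against no MuDR no Muk and F1 against MuDR only gave 1 each. F1 against no MuDR no Muk gave 33 with array weights, and F1 against MuDR only gave 4 with a pseudocount of 5 and 79 with edgeR. Without each library in turn the counts ran from 0 to 668 for MuDR only and 0 to 966 for Muk only against no MuDR no Muk, 0 to 5 for F1 against it, 0 to 616 for F1 against MuDR only, 0 to 0 for F1 against Muk only, 0 to 1 for leaf 6 and 0 to 0 for the interaction. Muk only against no MuDR no Muk gave 966 without MuDR only replicate 1, 698 without MuDR only replicate 2, 434 without leaf 6 replicate 2 and 337 without leaf 6 replicate 1, and 0 without either replicate of no MuDR no Muk, Muk only or F1 leaf 2. MuDR only against no MuDR no Muk gave 117 without its replicate 2 and 4 without leaf 6 replicate 2. F1 against no MuDR no Muk gave its 5, and leaf 6 its 1, without leaf 6 replicate 2.

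For families, Muk only against no MuDR no Muk (1) gave 0 with a pseudocount of 5, with median-of-ratios scaling and with the covariate, 19 with array weights, 2 with 3' variants and 8 without both doubted libraries. Settings made for other features of the shared fit also ended it, by a larger SE at the same log2 fold change of 5.19: the share of 20 to 24 nt (adjusted p 0.0976), TIR runs of 16 and 20 nt (0.110 and 0.134) and the extended repeat (0.0968). Without these libraries MuDR only and F1 against no MuDR no Muk gave 11 and 16, F1 against MuDR only 1, F1 against Muk only 4 and leaf 6 against leaf 2 gave 6. With 3 out, MuDR only, Muk only and F1 against no MuDR no Muk gave 23, 17 and 23, F1 against MuDR only 2, F1 against Muk only 5 and leaf 6 against leaf 2 gave 6 (1 higher, 5 lower). Without each library in turn the counts ran from 0 to 14 for MuDR only, 0 to 13 for Muk only and 0 to 9 for F1 against no MuDR no Muk, 0 to 2 for each of the 3 others, and 0 to 9 for the interaction (9 without MuDR only replicate 2, 1 without either leaf 6 library). Muk only against no MuDR no Muk gave 13 and 12 without MuDR only replicates 1 and 2, 2 without either leaf 6 library, and 0 without Muk only replicate 2 or either F1 leaf 2 library. MuDR only against no MuDR no Muk gave 14 without its replicate 2 and 1 without either leaf 6 library. F1 against no MuDR no Muk gave 9 without either MuDR only library, 2 without F1 leaf 2 replicate 1, and 1 without Muk only replicate 1 or either leaf 6 library. F1 against MuDR only gave 1 without MuDR only replicate 1 and 2 without F1 leaf 2 replicate 1, which also gave 2 against Muk only and for leaf 6, where leaf 6 replicate 2 left out gave 1.

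For the 24-nt class (log2), signs changed with the covariate for MuDR only (−0.1509) and F1 (−0.0947) against no MuDR no Muk and F1 against MuDR only (0.0562), with median-of-ratios scaling for Muk only (0.5236) and F1 against MuDR only (0.0225), and as a share of 20 to 24 nt for the same 2 (0.0046 and 0.0143). Without each library in turn it ran from −0.1727 to 0.2541, −0.2229 to −0.0841 and −0.2248 to 0.2539 for MuDR only, Muk only and F1 against no MuDR no Muk, −0.2655 to 0.2131 and −0.0712 to 0.4074 for F1 against MuDR only and Muk only, and −0.5422 to −0.0635 for leaf 6. TIR small RNAs changed sign for F1 against MuDR only with the extended repeat (0.8714) and without both doubted libraries or with 3 out (1.1096 each), and for F1 against Muk only with the covariate (0.0751) and without both doubted libraries or with 3 out (0.9738 each). Without each library in turn they ran from 0.546 to 2.0473, 0.4345 to 1.9359 and −0.9546 to 2.159 for MuDR only, Muk only and F1 against no MuDR no Muk, −2.2512 to 0.8624 and −2.1398 to 0.9738 for F1 against MuDR only and Muk only, and −2.3621 to 0.7516 for leaf 6, none of them past the threshold.

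Replicate numbers were not treated as pairs in the main fit. The deviations of same-numbered libraries correlated from −0.278 to 0.155. These values cannot settle whether the numbers mark pairs, since replicates of MuDR only and of both F1 groups also differed in library profile. A replicate block gave 2 tags for MuDR only against no MuDR no Muk, 310 for Muk only against it, 1 for the interaction, and 1 family for F1 against no MuDR no Muk. Depth limits MuDR only replicate 2 most, where 1 read is 7.79 RPM. In the fits without MuDR only replicate 1, that shallow library alone stood for its group.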

Other observations

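The tests of the 7 contigs above and the edgeR fits were chosen after the data were seen, and the values of this part come from no further test.

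The ends of the Mu elements gave small RNAs of several lengths. Of 93 reads matching the TIR primer sequence, 42 were 24 nt, 20 were 21 nt and 6 were 22 nt long, and all 20 reads of 21 nt ran inward. With the extended repeat, 182 of 315 reads were 24 nt and 37 were 21 nt. Reads of 21 nt were not seen in the no MuDR no Muk libraries, where 3 reads would be 2.38 and 2.44 RPM, or in the F1 leaf 6 libraries, where they would be 4.15 and 2.46 RPM, with either form of the repeat. Pooled over both libraries, the upper Poisson limits were 1.48 RPM in no MuDR no Muk and 1.90 RPM in F1 leaf 6. For the primer sequence the other groups pooled to 1.15 to 1.96 RPM, with intervals that start below these limits. With the extended repeat they pooled to 2.24 RPM in MuDR only (95% Poisson interval 0.969 to 4.42), 2.89 in Muk only (1.61 to 4.76) and 3.09 in F1 leaf 2 (1.69 to 5.19). F1 leaf 2 replicate 1 also had 0 reads of 21 nt for the primer sequence. The extended reads of all lengths amounted to 3.61 RPM pooled over no MuDR no Muk (95% Poisson interval 1.65 to 6.86), 10.9 over MuDR only (7.78 to 15), 23.7 over Muk only (19.7 to 28.2), 28.3 over F1 leaf 2 (23.6 to 33.6) and 8.24 over F1 leaf 6 (4.71 to 13.4). These pooled intervals leave out the spread between replicates, which was 7.22 and 42.2 RPM in F1 leaf 2.

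The 142 contigs of 22-nt tags other than the 7 held 5687 RPM in MuDR only replicate 1, 1348 in MuDR only replicate 2, 3925 and 2755 in Muk only, 1192 and 5294 in F1 leaf 2, 464 and 678 in F1 leaf 6, and 469 and 687 in no MuDR no Muk. Only 1 tag of the 15724 tested lies in the 7 contigs, so the tag test could not report on them.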
